A study of Caenorhabditis elegans with 14 samples.

How the data were processed

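RNA was sequenced from early embryos of the nematode Caenorhabditis elegans in 14 samples of 4 genotypes. Per the labels' protocols, total RNA was depleted of ribosomal RNA and made into libraries with a kit that keeps the strand of each transcript. Reads were trimmed with Trimmomatic 0.39 and the genome build was ce10, per the submitters' processing notes. The aligner, the program that counted reads, its use of strand and the gene annotation are not given in the sources used here. Since the use of strand in the counting was not stated, values of overlapping and antisense genes are uncertain. The same holds for near-identical copies such as replication-dependent histone genes, and for members of large families such as the F-box genes. Of the named genes, ins-13 and acdh-2 overlap on the same strand, as do syp-1 and F13A7.14.

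The deposited table holds raw counts per gene for 20392 genes in 14 columns, with the width of each gene in bases beside them. Every column name matched the title of a single sample, and no column of sample values was left out. The columns were whole numbers with totals that differed between libraries, and no normalization by the authors was found in them. Gene symbols, chromosomes, positions and gene types came from a reference annotation of the WBcel235 assembly, matched by gene identifier. Of the 20392 identifiers, 19870 were in that annotation and 19182 had a symbol there. Positions printed here are those of WBcel235 and were not converted to ce10.

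Groups followed the genotype in the labels, with 3 wild-type, 4 hpl-2 mutant, 4 hpl-2-FFAA and 3 met-2 hpl-2 libraries. Totals ran from 5332725 to 6390870 counts in the first 3 groups and from 14313366 to 14840992 in met-2 hpl-2. A limit of 3 counts, the most that a count of 0 allows, corresponded to 0.202 to 0.563 CPM, the counts scaled to a common library total. Intervals and limits of this kind cover counting error only. Replicates were compared in pairs by a chi-square test of counts over genes with a summed count of at least 20. All 18 pairs differed beyond sampling noise, so each library was counted as a separate sample. The labels do not say that replicates were separate cultures, and p-values measure the spread between these samples, which may be technical.

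Differences were tested with edgeR 4.0.16 under R 4.3.3, using its low-count filter, TMM scaling and the quasi-likelihood test on the deposited counts. All 14 libraries entered a single fit of 4 groups, which share an estimate of the spread, and 9498 genes passed the filter. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, separately in each of 5 comparisons. The square root of the common dispersion was 5.34%. Standard errors (SE) of log2 fold changes were the size of the log2 fold change divided by the square root of its F statistic. Levels are given as TMM-normalised CPM, mean ± SD.

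Genes were named by a rule fixed before the data were examined. It took hpl-2 and met-2 in every comparison. It then took the 6 highest and 6 lowest fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between the replicates. From each gene list with a call, or with at least 3 called members, it took the 2 called members of smallest adjusted p, up to about 30 genes per comparison. Other genes are named as chosen after their values were seen.

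In the same way 26 gene lists were written from textbook knowledge, with 480 members, of which 452 were found in the table. They covered chromatin factors, germline and maternal genes, zygotic genes, tissues, stress and immune families, ribosomal protein and histone genes, and markers of adult worms. The vitellogenin list, a marker of adult intestine, had fewer than 3 tested members and was not tested. The other 25 were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, two-sided, and the 125 p-values were adjusted together. An estimated correlation and fry were the alternatives. Under the estimated correlation 0 of the 55 camera calls were kept. The heterochromatin and synMuv lists hold hpl-2 and met-2, the mutated genes. Without them 48 calls were left, none of them in these lists, so their calls are not given. Counts of called members are given over all genes tested and adjusted over the list alone.

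After seeing the data, an axis of differences between replicates was taken as the first principal component of log2 CPM after subtraction of each group's mean (28.2% of that variance). Scores on it ran from -22.6 to 17 in hpl-2-FFAA and from -13.7 to 9.37 in the hpl-2 mutant. They ran from -5.93 to 4.31 in met-2 hpl-2 and from -1.73 to 3.33 in wild type. The axis was removed from fold changes by regression over the 5740 genes with a mean of at least 20 CPM. Since mutant libraries set most of it, its removal may also take away mutant effects that vary between replicates.

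Comparisons that share the 3 wild-type libraries were set beside 100 simulations of unchanged groups. Another 100 kept the hpl-2 mutant effects, with the other mutant groups at the wild-type mean. All 14 libraries were drawn anew each time, so comparisons shared simulated wild-type libraries, not the real ones. Genes were drawn independently with the same spread in each group, without the differences between replicates that genes share. Simulated ranges may therefore be too narrow. Chromosome arms were taken as the outer 30% of each end of an autosome, and shares of called genes on arms were tested by Fisher's exact test, two-sided, with 20 tests adjusted together. For genes with 1 to 3 counts in a group, the ratio of summed counts is given with an exact conditional 95% interval.

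The test was tried on simulated counts for the 9498 genes with 200 genes changed by known folds. Of genes changed 1.5-fold, 73.1% were recovered in hpl-2 mutant against wild type, 73.1% in hpl-2-FFAA against wild type and 73.1% in met-2 hpl-2 against wild type. For hpl-2-FFAA against hpl-2 mutant the share was 70.1%, and for met-2 hpl-2 against hpl-2 mutant 77.6%. Of genes changed 2-fold, 88.1%, 80.6%, 92.5%, 89.6% and 89.6% were recovered in the same order. False calls made up 2.79%, 4.05%, 6.38%, 5.59% and 6.88% of all calls in these simulations. In a simulation with 1 shifted list, camera called 1 list, the shifted one. Genes were drawn independently there, so it does not test false list calls among correlated genes.

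Alternatives chosen before the data were examined were other scalings, no filter and a stricter filter (at least 5 CPM in 3 samples), DESeq2 1.42.0, fits of only the groups compared, the replicate number as a block, and leaving out each library. Chosen after seeing the data were fits without parts of the hpl-2-FFAA group, met-2 hpl-2 libraries thinned to 5878804 counts, removal of each library's trend with gene width, only genes of at least 1000 bases, and the heterochromatin and synMuv lists without hpl-2 and met-2.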

Results

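Gene expression was measured by RNA sequencing in early C. elegans embryos grown at 20 °C. Wild-type embryos (strain N2, n = 3) were compared with embryos of 3 mutant strains. The hpl-2 mutant (n = 4) carries the tm1489 deletion of hpl-2, which encodes an HP1 protein, a chromatin protein of the kind that binds methylated histone H3 lysine 9. The strain named hpl-2-FFAA (n = 4) carries the px112 allele of the same gene. The met-2 hpl-2 strain (n = 3) carries the tm1489 deletion together with the n4256 allele of met-2, which encodes an H3K9 methyltransferase, and is kept over the hT2 balancer chromosome. Wild-type libraries held 5846490 to 6032200 counts, hpl-2 mutant libraries 5497160 to 6390870 and hpl-2-FFAA libraries 5332725 to 6059674. The met-2 hpl-2 libraries held 14313366 to 14840992, so low transcripts were measured more precisely in that group. Between 13334 and 14039 genes had at least 1 count in the first 3 groups, against 15836 to 16297 in met-2 hpl-2.

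The mutated genes themselves were read first. Transcripts of hpl-2 (WBGene00001996, chromosome III, 10752195 to 10755530 on the minus strand of WBcel235) stood at 95.9 ± 5.46 CPM in wild type (SD, n = 3). They stood at 4.41 ± 0.693 CPM in the hpl-2 mutant (n = 4), 65.3 ± 3.29 CPM in hpl-2-FFAA (n = 4) and 10.03 ± 1.30 CPM in met-2 hpl-2 (n = 3). These are 4.6%, 68.1% and 10.5% of the wild-type level. Transcripts of met-2 (WBGene00019883, chromosome III, 8375300 to 8380848 on the plus strand) stood at 287.7 ± 8.83 CPM in wild type, 265.3 ± 5.92 in the hpl-2 mutant, 282.7 ± 6.16 in hpl-2-FFAA and 29.4 ± 1.81 in met-2 hpl-2. The last is 10.2% of wild type. All libraries of each mutant lay below all wild-type libraries for the gene or genes mutated in that strain.

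**Figure D1:**
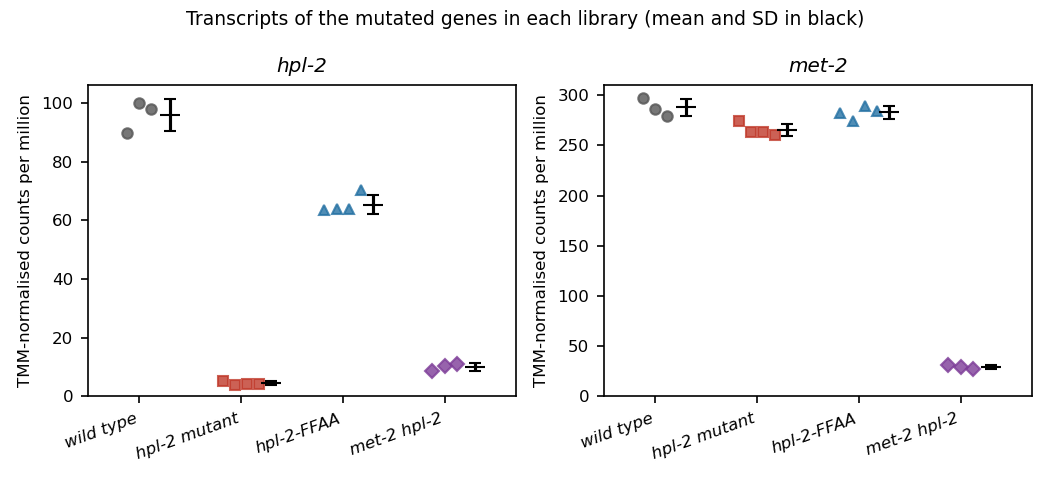
TMM-normalised CPM of hpl-2 (left) and met-2 (right) in each of the 14 libraries, by genotype, with group mean and SD in black. The hpl-2 transcript lies at 4.41 CPM in the hpl-2 mutant and 65.3 CPM in hpl-2-FFAA against 95.9 CPM in wild type, and met-2 is low in the met-2 hpl-2 libraries, at 29.4 CPM.

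On the first principal component of log2 CPM (54.2% of the variance) the met-2 hpl-2 libraries lay apart from all others. The second (21.1%) set hpl-2 mutant libraries apart from wild type, with hpl-2-FFAA replicates 1 and 2 near wild type and replicates 3 and 4 between wild type and the hpl-2 mutant. Within hpl-2-FFAA, the chi-square per degree of freedom between libraries was 2.22 for replicates 1 and 2, 1.11 for replicates 3 and 4 and 8.51 for replicates 2 and 3. It was 1.17 to 1.28 within wild type, 1.16 to 3.66 within the hpl-2 mutant and, with more counts per library, 2.82 to 6.68 within met-2 hpl-2. All F-box, ribosomal and germline values of hpl-2-FFAA given here average over that spread.

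**Figure D2:**
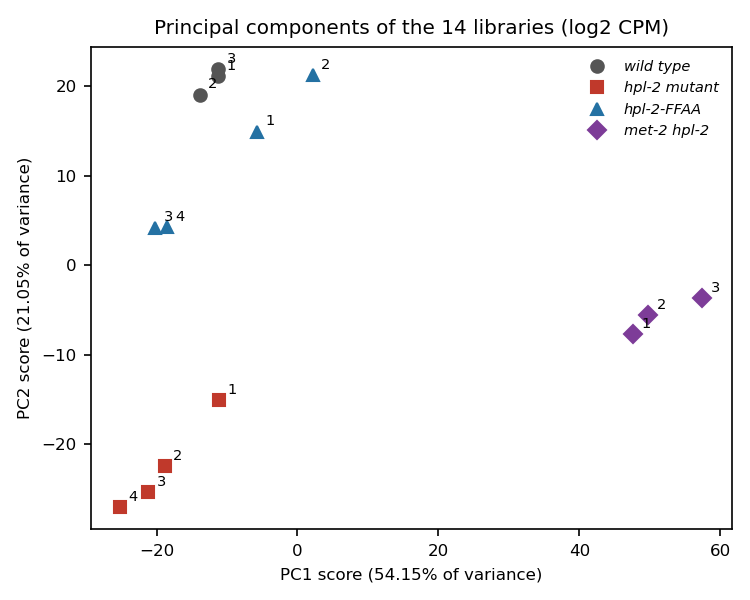
Scores of the 14 libraries on the first principal components of log2 CPM, with the replicate number beside each point. PC1 holds 54.2% of the variance and parts met-2 hpl-2 from the rest, and PC2 holds 21.1% and parts the hpl-2 mutant from wild type, with hpl-2-FFAA replicates 3 and 4 between them.

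Loss of HPL-2 addresses which genes depend on this HP1 protein. In the hpl-2 mutant the largest rises were in genes that were nearly silent in wild type. C55C3.3 rose by 5.83 on the log2 scale (SE 0.307), from 0.558 ± 0.593 CPM to 32.8 ± 4.05 CPM. K10G9.2 rose from 1.40 ± 0.213 to 27.9 ± 2.81 CPM (log2 4.30, SE 0.221), and C09G5.7 and Y47G6A.5 rose by 4.44 (SE 0.313) and 4.43 (SE 0.276). The ciliary gene dyf-3 rose by 3.99 (SE 0.33) and klf-1, which encodes a Krüppel-like transcription factor, by 3.70 (SE 0.322). Heat shock genes led the genes that fell: hsp-16.41 fell from 13.9 ± 3.82 to 1.81 ± 1.22 CPM (log2 -2.95, SE 0.346), and hsp-16.2 by 2.64 (SE 0.299). F44E5.5 and F44E5.4, near-identical Hsp70-family genes whose counts may share reads, had log2 fold changes of -3.30 (SE 0.542) and -2.76 (SE 0.513). The labels' extract protocol speaks of embryos exposed to stated temperatures before extraction, while the growth labels give 20 °C, and how each group was handled is not given in the sources used here, so the handling behind the heat shock values is not known. The neuroendocrine gene ida-1 fell by 2.58 (SE 0.267). The naming rule took only called genes whose 4 mutant and 3 wild-type libraries did not overlap. Adjusted p of these genes ran from 1.46e-10 (K10G9.2) to 0.000375 (F44E5.4) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fall of hpl-2 itself was -4.44 (SE 0.108, adjusted p = 1.58e-15 in the same edgeR test with Benjamini-Hochberg adjustment). The met-2 transcript was lower by a log2 of -0.12 (SE 0.0404, adjusted p = 0.0274 in that test with the same adjustment), and that call was lost without wild-type replicate 1 or 2 or hpl-2 mutant replicate 2, 3 or 4 (adjusted p = 0.0598 to 0.131 in the same edgeR test with Benjamini-Hochberg adjustment), with library size alone (0.0636) and with no low-count filter (0.0666).

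Germline and maternal genes were more often higher than lower in the hpl-2 mutant. Of 43 tested genes of germline P granules and meiosis, 34 rose and 1 fell, or 36 and 1 adjusted over the list alone. The synaptonemal complex gene syp-1 rose by 0.70 (SE 0.0629) and the chromosome axis gene htp-3 by 0.59 (SE 0.0652). Of 33 maternal oocyte and one-cell genes 19 rose and 0 fell (21 and 0 adjusted over the list alone), among them gld-3 (log2 0.44, SE 0.0661) and pie-1 (0.45, SE 0.0688), both needed in the germ lineage. Small RNA pathway genes rose in 15 cases and fell in 6 of 32, and spermatogenesis genes rose in 4 and fell in 0 of 11. Camera with Benjamini-Hochberg adjustment gave an adjusted p = 3.8e-11 for germline, 7.34e-06 for maternal, 0.021 for small RNA and 0.0378 for spermatogenesis genes. With an estimated correlation the adjusted p of these camera tests was 0.452, 0.514, 0.465 and 0.383.

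Zygotic, patterning and several large family lists had more members lower than higher, and under 50% of the F-box, xenobiotic and ribosomal members were called lower. Of 35 early zygotic and specification genes 19 fell and 1 rose, including sdz-28 (log2 -0.62, SE 0.0529) and the T-box gene tbx-8 (-0.80, SE 0.0994). Of 219 F-box, MATH and BATH genes, which encode substrate adaptors of ubiquitin ligases, 95 fell and 26 rose, or 101 and 29 adjusted over the list alone. Examples were fbxb-75 (-0.81, SE 0.0732) and fbxc-18 (-0.63, SE 0.0700). Of 19 Hox and homeobox genes 10 fell and 1 rose, with ceh-43 at -0.57 (SE 0.0910) and unc-62 at -0.45 (SE 0.0767). Xenobiotic metabolism families had 35 members lower and 7 higher of 92, including dhs-8 (-0.86, SE 0.0957) and the transporter gene pgp-2 (-0.56, SE 0.0626). Ribosomal protein genes had 28 lower and 2 higher of 75 (27 and 2 adjusted over the list alone), with rpl-43 at -0.43 (SE 0.0775) and rps-18 at -0.25 (SE 0.0477). Somatic gonad and vulva genes fell in 10 cases and rose in 2 of 19, among them the Notch receptor gene lin-12 (-0.53, SE 0.0581) and the TCF gene pop-1 (-0.48, SE 0.0623).

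Heat shock genes fell in 7 and rose in 4 of 15, sex determination and X dosage compensation genes fell in 8 and rose in 4 of 18, and synMuv B and DREAM genes fell in 6 and rose in 3 of 22. Heterochromatin and H3K9 methylation factors fell in 7 and rose in 3 of 23. Among them cec-8, which encodes a chromodomain protein, fell by 0.69 (SE 0.0712). The last 2 lists hold hpl-2 itself, and without hpl-2 and met-2 neither had a camera call (adjusted p = 0.52 for heterochromatin and 0.861 for synMuv genes after Benjamini-Hochberg adjustment, with means of -0.0439 and -0.0256). Adjusted p from camera with Benjamini-Hochberg adjustment was 9.81e-06 for F-box, 0.000271 for early zygotic, 0.00318 for ribosomal, 0.00336 for xenobiotic, 0.00379 for Hox, 0.0105 for gonad, 0.0141 for heat shock and 0.0493 for sex determination genes, the last at 0.0553 with the lists that lack hpl-2 and met-2. With an estimated correlation the adjusted p of the camera tests lay at 0.276 for early zygotic genes, 0.406 for F-box genes and 0.68 for ribosomal genes. It lay between 0.452 (heat shock) and 0.499 (Hox and sex determination) for the others.

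No camera call was made in this comparison for bZIP, oxidative and ER stress genes (3 higher and 8 lower of 20), body muscle (4 and 8 of 25), chemoreceptors (4 and 7 of 53), epidermis and cuticle collagens (5 and 3 of 39), immune effectors (3 and 7 of 35), intestine (1 and 6 of 17), the intracellular pathogen response (0 and 1 of 7), mitochondrially encoded genes (2 and 2 of 12), neurons (1 and 8 of 26), pharynx (0 and 4 of 12) or replication-dependent histones (4 and 8 of 29). Adjusted over the list alone, no count of a list other than F-box genes differed by more than 3 from these. The vitellogenin genes, transcribed in adult intestine, summed to 1.93 to 3.09 CPM in hpl-2 mutant libraries and 2.49 to 3.4 CPM in wild type. In all, 3968 of 9498 genes were called, 1915 higher and 2053 lower, of which 217 and 155 differed at least 2-fold. The median size of a called change was a log2 of 0.363. The libraries of both groups did not overlap for 49% of tested genes, where chance gives 5.71%. X-linked genes had a median log2 fold change of -0.22 in this comparison, and the X share of counts was 5.69% to 6.29% in the mutant against 6.96% to 7.15% in wild type. Differences between replicates ran along the same axis as this comparison (r = 0.71 across 5740 genes, which are not independent replicates), signed so that maternal genes lie above 0. An axis from the hpl-2-FFAA libraries alone gave r = 0.68, and one from the wild-type and met-2 hpl-2 libraries alone r = 0.107. The medians given here have the axis of all 14 libraries removed, which may also take away mutant effects that vary between replicates. With that axis removed the median of germline genes went from 0.38 to 0.153, of maternal genes from 0.25 to 0.0647, of Hox genes from -0.49 to 0.0168, of gonad genes from -0.48 to -0.102 and of X-linked genes from -0.22 to -0.0333. Xenobiotic genes went from -0.42 to -0.121, ribosomal genes from -0.14 to 0.0295, F-box genes from -0.28 to -0.185 and early zygotic genes from -0.21 to -0.168. Small RNA genes went from 0.13 to 0.0341, spermatogenesis genes from 0.41 to 0.14, sex determination genes from -0.15 to -0.0202 and heat shock genes from -0.24 to -0.183.

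The px112 allele addresses how far hpl-2-FFAA resembles loss of the protein. In hpl-2-FFAA embryos few genes passed the threshold, and most of the largest rises were smaller than in the deletion. The largest was that of dyf-3 (log2 2.48, SE 0.413), below 5 CPM here and so outside the naming rule for this comparison. K10G9.2 rose to 5.38 ± 1.66 CPM from 1.40 ± 0.213 CPM (log2 1.95, SE 0.298). Y55F3BR.2 rose by 1.52 (SE 0.155), Y105C5B.20 by 1.29 (SE 0.203), the receptor guanylyl cyclase gene gcy-19 by 1.21 (SE 0.188), samt-1 by 1.17 (SE 0.222) and the neuropeptide receptor gene npr-37 by 1.15 (SE 0.191). Of these, gcy-19 rose by 1.37 (SE 0.183) in the deletion. The direct test did not call it different between the alleles (adjusted p = 0.398 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among genes that fell, fbxa-170 had a log2 fold change of -0.83 (SE 0.0906), hpl-2 itself -0.55 (SE 0.0720) and rgs-9, a regulator of G protein signalling, -0.54 (SE 0.0903). The F-box genes fbxb-84 and fbxb-82 had values of -0.42 (SE 0.0642) and -0.40 (SE 0.0884), and sdz-14 of -0.36 (SE 0.0693). Adjusted p for these genes ran from 1.61e-05 (Y55F3BR.2) to 0.0391 (fbxb-82) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In that edgeR test with Benjamini-Hochberg adjustment samt-1 lost its call without wild-type replicate 2 or 3 (adjusted p = 0.0762 and 0.106), sdz-14 without wild-type replicate 1 or 2 (0.0832 and 0.0847) and fbxb-82 without any wild-type replicate or hpl-2-FFAA replicate 2, 3 or 4 (0.0698 to 0.231). With only the groups compared rgs-9 and fbxb-84 (both adjusted p = 0.0508), samt-1 (0.0894) and fbxb-82 (0.213) lost theirs in that edgeR test with Benjamini-Hochberg adjustment. With hpl-2-FFAA replicates 1 and 2 alone samt-1, fbxb-82 (both adjusted p = 0.0966) and sdz-14 (0.0825) did, and with no low-count filter fbxb-82 (0.0542), in the same edgeR test with Benjamini-Hochberg adjustment. The met-2 transcript gave a log2 value of -0.03 (SE 0.0404, adjusted p = 0.908 in the same edgeR test with Benjamini-Hochberg adjustment).

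Of 219 F-box, MATH and BATH genes 6 were called lower and 0 higher in hpl-2-FFAA (14 and 0 adjusted over the list alone), with a median log2 of -0.13. Their adjusted p was 2.18e-09 in camera with Benjamini-Hochberg adjustment and 0.276 with an estimated correlation. With hpl-2-FFAA replicates 3 and 4 alone 31 of them fell and 1 rose, and with replicates 1 and 2 alone 2 fell. Ribosomal protein genes had a median of 0.10 with 1 of 75 called, rpl-25.2 (0.31, SE 0.0498). Early zygotic genes had a median of -0.10, with sdz-28 (-0.28, SE 0.0523) and vet-6 (-0.16, SE 0.0370) called lower of 35. Both calls were lost with only the groups compared (adjusted p = 0.0709 and 0.171 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) and without wild-type replicate 1, 2 or 3 (0.0664, 0.0635 and 0.0982 for sdz-28, 0.149, 0.311 and 0.106 for vet-6). With hpl-2-FFAA replicates 1 and 2 alone they were lost too (adjusted p = 0.0519 and 0.175), and vet-6 lost its call without hpl-2-FFAA replicate 3 or 4 (0.126 and 0.121), with scaling by library size alone (0.0551) and under the stricter filter (0.0573), in the same edgeR test with Benjamini-Hochberg adjustment. Camera with Benjamini-Hochberg adjustment gave an adjusted p = 4.89e-09 for ribosomal and 0.000234 for early zygotic genes, and 0.465 and 0.276 as the adjusted p with an estimated correlation. Maternal genes (median 0.07, 0 of 33 called) and germline genes (median 0.06, with the P granule gene meg-4 lower by -0.34, SE 0.0775, of 43) had camera adjusted p of 0.0277 and 0.038 after Benjamini-Hochberg adjustment, and 0.762 and 0.764 with an estimated correlation. The call of meg-4 was lost without any wild-type replicate or hpl-2-FFAA replicate 1, 2 or 3 (adjusted p = 0.0662 to 0.275 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was lost too with only the groups compared (adjusted p = 0.167), with hpl-2-FFAA replicates 3 and 4 alone (0.0775), with RLE size factors (0.0512) and with library size alone (0.0595), in the same edgeR test with Benjamini-Hochberg adjustment. In the other 20 lists camera made no call and at most 1 member was called each way. Called members there were hpl-2, which stands in both the heterochromatin and synMuv lists, and the synMuv gene lin-15B (0.17, SE 0.0308), named after its value was seen. Adjusted over the list alone, counts of lists other than F-box genes differed by at most 1. With the replicate axis removed the median of germline genes went from 0.06 to 0.0316 and of maternal genes from 0.07 to 0.047. F-box genes went from -0.13 to -0.115, early zygotic genes from -0.10 to -0.0782 and ribosomal genes from 0.10 to 0.113.

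In total 74 genes were called in hpl-2-FFAA, 52 higher and 22 lower, of which 12 and 0 differed at least 2-fold, against 933 with an unadjusted p under 0.05. Leaving out wild-type replicate 1, 2 or 3, which leaves 2 wild-type libraries each time, gave 31, 26 or 33, and leaving out hpl-2-FFAA replicate 2 or 4 gave 108 or 44. With replicates 3 and 4 of hpl-2-FFAA alone it was 820 (332 higher and 488 lower, 71 of the 74 among them), and with replicates 1 and 2 alone 49 (35 of the 74), pairs chosen because they lay apart on the principal components. A fit of only the groups compared called 24, and another split of these libraries called 280.

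The direct comparison of hpl-2-FFAA with the hpl-2 mutant tests the difference between both alleles. Genes nearly silent in wild type were lower in hpl-2-FFAA than in the deletion: C55C3.3 stood at 1.55 ± 0.281 against 32.8 ± 4.05 CPM (log2 -4.39, SE 0.228), C09G5.7 at -3.47 (SE 0.246), Y47G6A.5 at -2.86 (SE 0.199) and klf-1 at -2.73 (SE 0.252). The kinase gene dlk-1, known for its part in axon regeneration, stood at 7.998 ± 3.05 against 62.8 ± 7.31 CPM (-2.99, SE 0.147), and nekl-1 at -2.72 (SE 0.233). The heat shock genes F44E5.5 (3.46, SE 0.505), F44E5.4 (3.07, SE 0.467), hsp-16.41 (2.98, SE 0.328) and hsp-16.2 (2.62, SE 0.285) were higher in hpl-2-FFAA, as was R193.2 (1.77, SE 0.210). hsp-16.41 stood at 14.2 ± 2.85 CPM in hpl-2-FFAA, beside 13.9 ± 3.82 in wild type. The hpl-2 transcript was higher by 3.88 (SE 0.108), while met-2 had a log2 of 0.09 (SE 0.0376, adjusted p = 0.0661). Adjusted p of the named genes other than met-2 ran from 2.07e-14 (hpl-2) to 0.00013 (F44E5.4), all from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

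Germline and maternal genes were lower in hpl-2-FFAA than in the deletion. Germline genes were lower in 31 and higher in 0 of 43 (syp-1 -0.56, SE 0.0571, htp-3 -0.53, SE 0.0598), and maternal genes lower in 19 and higher in 1 of 33 (gld-3 -0.35, SE 0.0607, pie-1 -0.36, SE 0.0631). Ribosomal protein genes were higher in 53 and lower in 0 of 75 (rpl-28 0.43, SE 0.0605, rps-28 0.62, SE 0.111), xenobiotic genes higher in 30 and lower in 4 of 92 (dhs-8 0.98, SE 0.0888, dhs-9 0.52, SE 0.0585). Hox and homeobox genes were higher in 10 and lower in 1 of 19 (ceh-43 0.50, SE 0.0854, unc-62 0.39, SE 0.0717), and F-box genes higher in 69 and lower in 27 of 219 (fbxb-75 0.66, SE 0.0695, fbxb-8 1.16, SE 0.146). Early zygotic genes were higher in 13 and lower in 1 of 35 (tbx-8 0.70, SE 0.0941, sdz-28 0.34, SE 0.0501), and gonad genes higher in 11 and lower in 2 of 19 (pop-1 0.45, SE 0.0583, hnd-1 0.55, SE 0.0802). Heat shock genes were higher in 7 and lower in 3 of 15, sex determination 9 and 3 of 18, small RNA 5 and 13 of 32 and spermatogenesis 0 and 4 of 11. Adjusted p over these 12 lists ran from 1.7e-12 (germline) to 0.038 (spermatogenesis and sex determination) in camera with Benjamini-Hochberg adjustment, and with an estimated correlation the adjusted p ran from 0.383 (spermatogenesis) to 0.514 (maternal). The heterochromatin list had 8 higher and 3 lower of 23 (cec-8 0.54, SE 0.0670) and the synMuv list 7 and 3 of 22 (mep-1 0.45, SE 0.0551). Both lists hold hpl-2, and without hpl-2 and met-2 they had no camera call (adjusted p = 0.241 and 0.5 after Benjamini-Hochberg adjustment). Adjusted over the list alone, counts differed by at most 6.

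Fold changes between the alleles ran along the axis on which replicates differ (r = -0.759 across 5740 genes, which are not independent replicates), while an axis from the wild-type and met-2 hpl-2 libraries alone gave r = -0.127. With that axis removed the median of germline genes went from -0.32 to -0.104, of maternal genes from -0.20 to -0.027, of ribosomal genes from 0.24 to 0.10 and of xenobiotic genes from 0.38 to 0.0726. Hox genes went from 0.50 to 0.0485, F-box genes from 0.15 to 0.0577, early zygotic genes from 0.18 to 0.0928 and gonad genes from 0.30 to 0.0786. Heat shock genes went from 0.28 to 0.153, sex determination genes from 0.13 to 0.00476, small RNA genes from -0.10 to -0.0159 and spermatogenesis genes from -0.19 to -0.0498.

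In all 3345 genes were called between the alleles, 1775 higher and 1570 lower in hpl-2-FFAA, of which 108 and 99 differed at least 2-fold. With hpl-2-FFAA replicates 3 and 4 alone the count was 1482, with ribosomal genes higher in 24, xenobiotic genes in 9, Hox genes in 2, gonad genes in 5, early zygotic genes in 8, heterochromatin genes in 3 and synMuv genes in 4 cases, F-box genes higher in 35 and lower in 15, and the medians of these lists above 0 as before.

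The met-2 hpl-2 strain addresses which genes change when the H3K9 methyltransferase MET-2 is lost together with HPL-2. C38D9.2 rose from 2.12 ± 0.380 CPM in wild type to 204 ± 6.16 CPM (log2 6.58, SE 0.139), and acdh-1, which encodes an acyl-CoA dehydrogenase, from 1.56 ± 0.33 to 68.4 ± 2.91 CPM (5.44, SE 0.178). The cuticlin gene cut-2 had 430 counts against 1 in wild type, a ratio of 186 after scaling (95% interval 33.3 to 7381). F41F3.3 had 371 against 1 (ratio 161, 28.7 to 6370), the Patched-related gene ptr-4 281 against 1 (122, 21.7 to 4829) and ZK180.5 213 against 2 (46.2, 12.63 to 384). The genes that fell most were short: F43G9.13 had a log2 fold change of -4.86 (SE 0.258), the ubiquitin-like gene ubl-5 of -3.90 (SE 0.139), the ribosomal protein gene rpl-39 of -3.74 (SE 0.227), W03A5.6 of -3.47 (SE 0.227), WBGene00018597, which has no symbol, of -3.404 (SE 0.1) and ostf-4 of -3.30 (SE 0.276). Their widths were 492, 330, 247, 360, 315 and 176 bases. The targeted genes hpl-2 and met-2 had log2 values of -3.26 (SE 0.0885) and -3.29 (SE 0.0497). Adjusted p over these genes ran from 2.96e-19 (met-2) to 2.64e-06 (ZK180.5) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

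Muscle, epidermis, intestine, pharynx and chemoreceptor genes were more often higher than lower in the met-2 hpl-2 embryos. Of 25 body muscle genes 20 rose and 1 fell, including unc-52, which encodes perlecan (2.48, SE 0.163), and the myosin heavy chain gene myo-3 (4.90, SE 0.358). Of 39 epidermis and cuticle collagen genes 29 rose and 1 fell (30 and 1 adjusted over the list alone), with dpy-3 at 2.79 (SE 0.229) and dpy-17 at 2.20 (SE 0.203). Intestine genes rose in 9 and fell in 3 of 17, among them acdh-1 and the intermediate filament gene ifb-2 (2.16, SE 0.299). Pharynx genes rose in 9 and fell in 0 of 12 (peb-1 1.80, SE 0.252, tbx-2 1.03, SE 0.149), and chemoreceptor genes rose in 22 and fell in 1 of 53 (srh-71 1.69, SE 0.221, srh-233 2.82, SE 0.381). With the trend of expression on gene width removed, muscle genes still counted 19 higher and 2 lower, and epidermis genes 30 and 1. Under the stricter filter 10 chemoreceptor genes were higher and 1 lower, and 19 epidermis genes were higher and 1 lower. The vitellogenin genes of adult intestine summed to 3.28 to 4.58 CPM in met-2 hpl-2 against 2.49 to 3.4 CPM in wild type. Fold changes of this comparison had r = -0.438 with the axis on which replicates of all 4 groups differ (across 5740 genes, which are not independent replicates), and r = -0.0932 with an axis from the libraries of the groups compared here. With the axis of all 4 groups removed the median of muscle genes went from 1.48 to 1.01, of epidermis genes from 1.05 to 0.718, of pharynx genes from 0.67 to 0.137, of intestine genes from 0.60 to 0.119 and of chemoreceptor genes from 0.33 to 0.261.

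Replication-dependent histone genes rose in 26 and fell in 1 of 29, with his-63 at 2.23 (SE 0.0542) and his-5 at 3.88 (SE 0.143), and took 3.82% ± 0.245 of counts against 2.35% ± 0.0266 in wild type. Copies of these genes are alike in sequence, so the split of counts among them is uncertain. The met-2 hpl-2 libraries also differed from wild type in depth, and changes in them went with gene width, as given below. The histone rise cannot be told apart here from a difference in how the libraries were made. Ribosomal protein genes went both ways, with 47 higher and 17 lower of 75, a median of 0.44 and a mean of 0.17. With the replicate axis removed the ribosomal median was 0.232 and the histone median went from 0.63 to 0.44. The 2 of smallest adjusted p were lower, rps-29 by -2.01 (SE 0.0668) and rps-7 by -1.56 (SE 0.0685). The 20 ribosomal genes under 500 bases had an SD of log2 fold changes of 1.27, against 0.489 for the 55 wider ones. Heterochromatin factors rose in 5 and fell in 6 of 23, and synMuv B and DREAM genes rose in 11 and fell in 7 of 22, both lists holding met-2 and hpl-2. Without these genes neither list had a camera call (adjusted p = 0.877 and 0.216 after Benjamini-Hochberg adjustment). With scaling by library size alone these lists counted 4 and 15, and 5 and 9.

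Adjusted p from camera with Benjamini-Hochberg adjustment was 4.66e-23 for histone, 8.41e-08 for muscle, 2.84e-06 for epidermis, 2.25e-05 for ribosomal, 0.00824 for intestine, 0.0378 for chemoreceptor and 0.0407 for pharynx genes. With an estimated correlation the adjusted p of these camera tests was 0.276, 0.452, 0.276, 0.532, 0.477, 0.418 and 0.514. No camera call was made for neurons (13 higher and 2 lower of 26, with snb-1 at 0.48, SE 0.0538, and unc-119 at -0.41, SE 0.0601), immune effectors (14 and 3 of 35, with irg-7 at 2.74, SE 0.294, and clec-12 at 0.84, SE 0.0971), Hox genes (10 and 1 of 19), bZIP and stress genes (9 and 5 of 20), mitochondrially encoded genes (8 and 3 of 12), gonad genes (9 and 3 of 19), spermatogenesis (4 and 2 of 11), sex determination (6 and 4 of 18) or xenobiotic genes (19 and 21 of 92). The same holds for F-box (51 and 46 of 219), early zygotic (7 and 12 of 35), germline (11 and 14 of 43), maternal (8 and 6 of 33), small RNA (7 and 12 of 32), heat shock (4 and 5 of 15) and intracellular pathogen response genes (1 and 2 of 7).

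Adjusted over the list alone, counts of the 25 lists differed from these by at most 3. In all 5514 genes were called, 2725 higher and 2789 lower, of which 862 and 231 differed at least 2-fold. Scaled by library size alone the split was 2176 higher and 3592 lower of 5768. Genes under 500 bases were at least 2-fold lower in 14.9% and higher in 9.37% of 363 cases, and genes of 5000 bases or more lower in 0.647% and higher in 20.4% of 309.

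**Figure D3:**
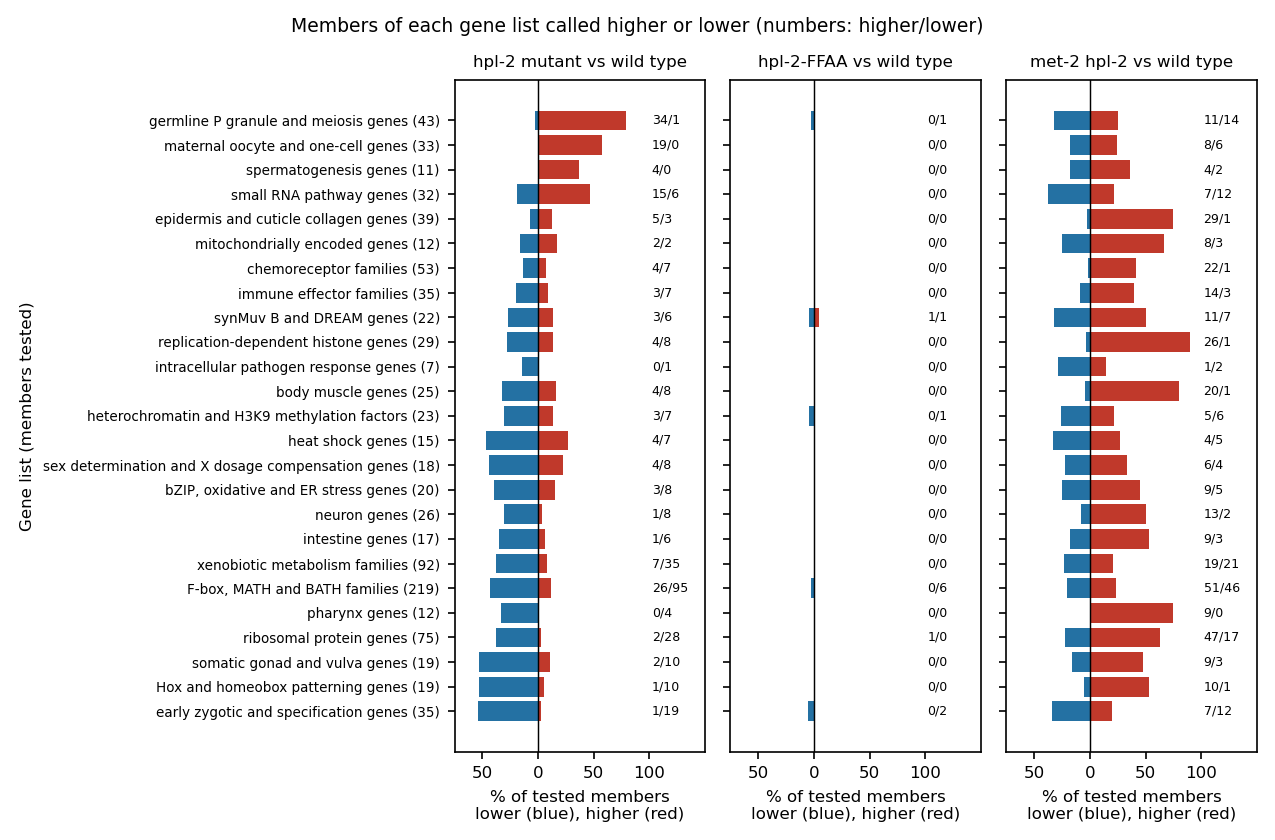
Percent of the tested members of each of 25 gene lists that were called higher (red, right) or lower (blue, left) than wild type in each mutant, with the counts higher/lower at the right of each panel and the members tested beside each name. Germline genes (34 of 43) lead the rises in the hpl-2 mutant, histone (26 of 29) and muscle genes (20 of 25) those in met-2 hpl-2, and no list has more than 6 called members in hpl-2-FFAA (F-box genes, of 219).

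The met-2 hpl-2 embryos were also compared directly with the hpl-2 mutant, since the series has no met-2 single mutant among these samples. The met-2 hpl-2 libraries were deeper (14313366 to 14840992 against 5497160 to 6390870 counts), and their strain is kept over the hT2 balancer. Genes of 5000 bases or more were at least 2-fold higher in 23.3% and lower in 0.971% of cases. What the met-2 allele adds cannot be told apart from these differences. acdh-1 stood at 68.4 ± 2.91 CPM against 0.530 ± 0.411 (log2 6.95, SE 0.191), acdh-2 at 25.02 ± 3.81 against 0.523 ± 0.306 (5.50, SE 0.245). The insulin-like peptide gene ins-13 had 25.6 ± 3.60 against 0.609 ± 0.349 CPM (5.33, SE 0.257). It overlaps acdh-2 on the same strand by 87 bases and has a width of 1805 in the deposited table for an annotated span of 353 bases, so its counts may be reads of acdh-2. C38D9.2 was higher by 4.59 (SE 0.0970). cut-2 had 430 counts against 1 (ratio 253, 95% interval 45.1 to 9997) and F41F3.3 had 371 against 1 (218, 38.9 to 8628). F43G9.13 had a log2 fold change of -5.07 (SE 0.240), ubl-5 of -3.89 (SE 0.133), W03A5.6 of -3.47 (SE 0.214) and ostf-4 of -3.42 (SE 0.255), all short genes, and C09G5.7 and K10B2.4 had -3.31 (SE 0.216) and -3.30 (SE 0.212). C09G5.7 stood at 1.48 ± 0.371 CPM in met-2 hpl-2 against 14.9 ± 2.18 in the hpl-2 mutant and 0.669 ± 0.285 in wild type. The hpl-2 transcript was higher by 1.18 (SE 0.140) than in the hpl-2 mutant, and met-2 was lower by -3.17 (SE 0.0480). Adjusted p ran from 3.01e-19 (met-2) to 6.32e-07 (hpl-2) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

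Muscle genes were higher in 24 and lower in 0 of 25 (unc-52 1.92, SE 0.136, unc-89 1.68, SE 0.128), epidermis genes higher in 29 and lower in 1 of 39 (dpy-3 2.77, SE 0.204, dpy-17 2.29, SE 0.185) and pharynx genes higher in 10 and lower in 0 of 12 (tbx-2 1.68, SE 0.146, ceh-32 1.03, SE 0.0996). Intestine genes were higher in 11 and lower in 3 of 17, among them acdh-1 and the junction gene dlg-1 (1.57, SE 0.154), and Hox genes higher in 16 and lower in 1 of 19, including the Pax gene vab-3 (1.92, SE 0.213) and ceh-13 (0.70, SE 0.0811). F-box genes were mostly higher, with 18 of 219 lower and 89 not called (fbxb-75 0.83, SE 0.0679, fbxa-192 1.03, SE 0.0925). Germline genes were lower in 30 and higher in 5 of 43, among them coh-3, which encodes a meiotic cohesin (-1.17, SE 0.0833), and the P granule gene deps-1 (-0.69, SE 0.0503), and maternal genes lower in 20 and higher in 2 of 33. Histone genes were higher in 25 and lower in 2 of 29 (his-63 2.20, SE 0.0489, his-5 4.12, SE 0.132), and ribosomal genes higher in 54 and lower in 14 of 75 (rps-2 0.93, SE 0.0404, rps-29 -1.91, SE 0.0635). Neuron genes were higher in 17 and lower in 1 of 26, gonad genes 13 and 3 of 19 and sex determination genes 12 and 4 of 18. Adjusted p over these 13 lists ran from 1.5e-19 (histone) to 0.038 (sex determination) in camera with Benjamini-Hochberg adjustment, and with an estimated correlation the adjusted p ran from 0.276 (histone) to 0.762 (maternal). Adjusted over the list alone, counts differed by at most 2. Fold changes of this comparison ran along the axis on which replicates differ (r = -0.75 across 5740 genes, which are not independent replicates), while an axis from the wild-type and met-2 hpl-2 libraries alone gave r = -0.135. With that axis removed the median of muscle genes went from 1.56 to 0.507, of epidermis genes from 1.14 to 0.333, of pharynx genes from 1.28 to 0.138, of intestine genes from 0.81 to -0.152 and of Hox genes from 1.03 to -0.023. F-box genes went from 0.29 to 0.0791, germline genes from -0.35 to 0.0262, maternal genes from -0.25 to 0.202, histone genes from 0.72 to 0.352 and ribosomal genes from 0.54 to 0.251. Neuron genes went from 0.53 to 0.26, gonad genes from 0.70 to 0.0395 and sex determination genes from 0.27 to 0.0115. In total 6765 genes were called, 3420 higher and 3345 lower, of which 1090 and 313 differed at least 2-fold. With scaling by library size alone 2846 were higher and 4017 lower of 6863.

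Genes at least 2-fold higher or lower without HPL-2 were then followed across the strains. The 217 genes at least 2-fold higher in the hpl-2 mutant had a median log2 fold change of 1.5 there. In hpl-2-FFAA their median was 0.68, with 205 of 217 above 0 and 22 called. In 100 simulations with hpl-2-FFAA at the wild-type mean and all libraries drawn anew, the median was 0.14 (0.0614 to 0.206). Genes were drawn independently there, so that range may be too narrow. The direct test placed 144 of the 217 genes nearer to wild type in hpl-2-FFAA than in the deletion and 0 further. The genes were selected on the same hpl-2 mutant libraries, which favours counts nearer to wild type in both direct tests, and these counts were not simulated. In met-2 hpl-2 their median was 1.61, with 185 called higher and 2 lower, and the direct test against the hpl-2 mutant placed 60 nearer to wild type and 77 further. The 155 genes at least 2-fold lower in the hpl-2 mutant had a median of -0.22 in hpl-2-FFAA (1 called, simulated median -0.11) and of -0.06 in met-2 hpl-2 (34 called lower and 32 higher).

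**Figure D4:**
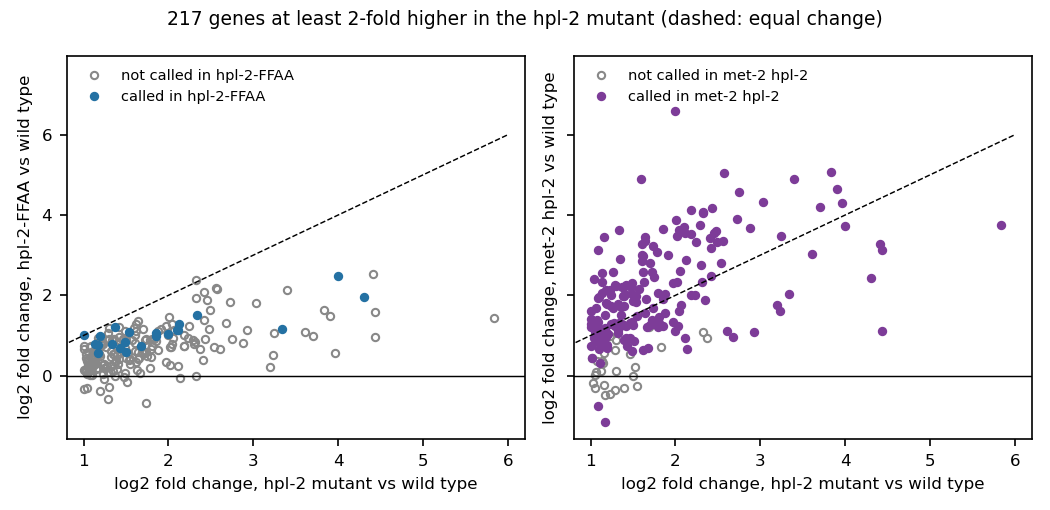
Log2 fold change against wild type of the 217 genes at least 2-fold higher in the hpl-2 mutant (horizontal) in hpl-2-FFAA (left) and met-2 hpl-2 (right), with filled points for genes called in that strain and a dashed line of equal change. In hpl-2-FFAA the median is 0.68 and 22 genes are called, and in met-2 hpl-2 the median is 1.61 and 187 are called, 2 of them lower.

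Of the 74 genes called in hpl-2-FFAA, 72 had the same direction in the hpl-2 mutant and 68 were called there in that direction. The direct test called 51 of them different between the alleles, with 45 nearer to wild type in hpl-2-FFAA. Across all tested genes the fold changes of hpl-2-FFAA and the hpl-2 mutant had r = 0.612 (rho 0.557), where simulated unchanged groups gave 0.572 on average and 0.6 at most. The share of genes changed in the same direction was 70.9%, against 69.3% on average and 70.9% at most in these simulations. The covariance was 0.0795 against a simulated 0.0203, a difference of 0.0592. Both comparisons called 49 genes higher, where independent lists would share 10.5, and 19 lower, against 4.76. The hpl-2 mutant and met-2 hpl-2 had r = 0.323 (0.608 simulated), which was 0.0906 among genes with a mean of at least 5 CPM, and rho was 0.0595, with 48.6% of genes changed in the same direction (70% simulated). Their covariance was 0.129 against 0.0202, with 614 genes higher in both (549 for independent lists), 567 lower in both (603), and 587 and 621 called in opposite directions. hpl-2-FFAA and met-2 hpl-2 had r = 0.418 (rho 0.21, r 0.604 simulated), 55.6% of genes changed in the same direction (69.9% simulated) and a covariance of 0.0844 against 0.0203, with 43 genes higher in both (14.9) and 8 lower in both (6.46). These values are across genes, which are not independent replicates, and 3 wild-type libraries could not be split, so part of any excess may come from the shared controls.

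Autosome arms, where H3K9 methylation is concentrated in this species, held 51.3% of the 8206 tested autosomal genes. Of genes at least 2-fold higher in the hpl-2 mutant, 139 of 188 lay on arms (odds ratio 2.76, 95% interval 1.97 to 3.91, adjusted p = 3.52e-10 by Fisher's exact test with Benjamini-Hochberg adjustment). In hpl-2-FFAA 10 of 10 did (adjusted p = 0.00267 by the same exact test and adjustment), and in met-2 hpl-2 472 of 695 (odds ratio 2.14, adjusted p = 7e-20 by the same exact test and adjustment). All genes called higher in the hpl-2 mutant, mostly small changes, were on arms in 43.4% of cases (odds ratio 0.667), and all called lower in 58.8% (odds ratio 1.46). Genes called lower in hpl-2-FFAA were on arms in 14 of 16 cases (odds ratio 6.67, 1.53 to 60.6) and those called higher in 26 of 37 (odds ratio 2.26, 1.08 to 5.06). With arms set at the outer 25% the share of the last group was 45.9% (adjusted p = 0.648 by Fisher's exact test with Benjamini-Hochberg adjustment), and that call was lost. Genes at least 2-fold lower in the hpl-2 mutant were on arms in 82 of 121 cases (67.8%, odds ratio 2.02, adjusted p = 0.000355 by Fisher's exact test with Benjamini-Hochberg adjustment). Those at least 2-fold lower in met-2 hpl-2 were on arms in 47.8% of cases (odds ratio 0.866, adjusted p = 0.335 by the same exact test and adjustment). The exact test treats genes as independent, while genes at least 2-fold higher in the hpl-2 mutant often lay next to each other. These p-values may therefore be too small and the intervals too narrow. Called and other tested genes were not matched on expression level.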

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

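The tests of other sample splits were fixed before their results were seen, and the other tests in this part were chosen only afterwards. In groups of 4 libraries, 8 of 195 tested values lay apart from the other 3, about as often as chance gives (about 1 in 20). The 195 were levels of named genes and library values such as total counts, and the 8 were all levels of named genes. The hpl-2 transcript stood at 70.27 CPM in hpl-2-FFAA replicate 4 against 63.52 to 63.78 in the others. In the hpl-2 mutant, replicate 1 stood apart for hsp-16.2 (1.419 CPM against 1.031 to 1.078), ceh-13 (70.97 against 63.41 to 64.37) and cut-2 (0.1577 against 0), and replicate 3 for K10B2.4 (7.387 against 10.03 to 10.25). F41F3.3 stood at 0.154 CPM in hpl-2 mutant replicate 2 and at 0.1696 CPM in hpl-2-FFAA replicate 3, against 0 in the others of each group. Ribosomal gene rps-29 stood at 106.2 CPM in hpl-2-FFAA replicate 2 against 99.33 to 100.1.

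Maternal and germline genes were more often called higher than lower in the hpl-2 mutant (19 and 0 of 33, and 34 and 1 of 43). Early zygotic genes were more often lower (19 lower and 1 higher of 35). The camera calls of these lists were not kept with an estimated correlation. Sequencing depth does not account for this pattern of calls, since mean totals of both groups had a ratio of 1.01. A difference in the mix of embryo ages stays a candidate. Across the 111 tested members of these lists, fold changes followed the axis along which replicates of a group differ with r = 0.732 (genes are not independent replicates). Nothing measured here ties that axis to age, and it was not told apart from mutant effects that vary between replicates. After removal of that axis the germline median went from 0.38 to 0.153, the maternal median from 0.25 to 0.0647 and the early zygotic median from -0.21 to -0.168. The 217 genes at least 2-fold higher kept a median of 1.5. The removal was fitted on genes with a mean of at least 20 CPM, and leading members such as C55C3.3, at 0.558 CPM in wild type, were low. The unchanged median therefore does not exclude the axis for them. Among lists without a camera call, the removal moved body muscle genes from -0.15 to 0.531 and epidermis genes from 0.08 to 0.35, farther from no change. It moved pharynx genes from -0.64 to 0.0711. Whether samples were collected at other ages or mutant embryos develop more slowly was not tested, and the axis built from wild-type and met-2 hpl-2 libraries alone gave r = 0.107 across 5740 genes.

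Of 363 genes under 500 bases 54 were at least 2-fold lower in met-2 hpl-2 and 34 at least 2-fold higher, against 2 and 63 of 309 genes of 5000 bases or more. Depth does not account for the short genes that were lower, since 92.6% of them (50 of 54) stayed so with the libraries thinned to the depth of the others. A length-dependent yield of short transcripts that differs between library preparations could. Ribosomal protein genes under 500 bases scattered 2.6 times as widely as wider ones (permutation p = 0.00011, 100000 permutations). They ran both ways, from -3.74 to 1.29, and include rpl-39, among the genes that fell most. The test therefore cannot tell a yield difference from a change in the embryos. That ratio was 1.11 in the hpl-2 mutant (permutation p = 0.319) and 1.51, with SDs of only 0.101 and 0.0667, in hpl-2-FFAA (permutation p = 0.0813). All met-2 hpl-2 libraries share the genotype, and a change in these transcripts in the embryos stays open and untested.

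The hpl-2 transcript was higher in met-2 hpl-2 than in the hpl-2 mutant, although both carry the same deletion. Depth does not account for this, since the log2 difference was 1.02 (SE 0.218) with thinned libraries. Wild-type RNA, such as that of embryos with intact copies on the balancer, could: met-2 stood at 10.2% of wild type (SD 0.629) in met-2 hpl-2, which is 4.38 percentage points more than the 5.85% by which hpl-2 exceeded its level in the hpl-2 mutant. What is left of the met-2 n4256 transcript without a balancer is not known from these samples, and a higher level of the deleted hpl-2 transcript itself was not tested.

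Other splits of the libraries were refitted for the 2 groups of each comparison. For the hpl-2 mutant against wild type the real split alone called as many genes (1 of 35, 4378 genes). That share, the smallest that 35 splits can give, is under 0.05 but does not exclude chance. The highest of the others called 2747. That highest count is large and points to a structure of the samples, with hpl-2 mutant replicate 1 placed with wild type. For hpl-2-FFAA against wild type, 2 of 35 splits called at least the 24 genes of the real one and the highest other called 280, so chance is not excluded. The split with 280 set wild-type replicates 1 and 3 with hpl-2-FFAA replicates 1 and 2, which again points to a structure of the samples. For met-2 hpl-2 against wild type there were 10 splits, too few for a share under 0.05, with 6151 genes in the real split, the 1 split of that size, and 0 in the highest other. For hpl-2-FFAA against the hpl-2 mutant the real split alone called as many genes (1 of 35, 2843 genes, highest other 0). The same held for met-2 hpl-2 against the hpl-2 mutant (1 of 35, 6741 genes, highest other 3212). Both shares are again the smallest that 35 splits can give.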

How the results depend on the processing

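The fits without parts of the hpl-2-FFAA group, with thinned libraries, with gene width and with lists without hpl-2 and met-2 were chosen after seeing the data. Counts of called genes in hpl-2 mutant against wild type, met-2 hpl-2 against wild type and met-2 hpl-2 against the hpl-2 mutant stayed within 1.5 times the reported count under every alternative run. The count for hpl-2-FFAA against wild type (74) was 820 with its replicates 3 and 4 alone, 49 with replicates 1 and 2 alone, 24 with only the groups compared and 43 with a replicate block; the cause was not tested. Leaving out each library gave 26 (without wild-type replicate 2) to 108 (without hpl-2-FFAA replicate 2). Between the alleles the count was 1482 with hpl-2-FFAA replicates 3 and 4 alone, and the cause was not tested. Leaving out libraries gave 3119 to 4020 for the hpl-2 mutant, 4920 to 5445 for met-2 hpl-2, 2511 to 3509 between the alleles and 6315 to 6678 for met-2 hpl-2 against the hpl-2 mutant. DESeq2 called 3507, 91, 5370, 2979 and 6662 genes in the order hpl-2 mutant, hpl-2-FFAA and met-2 hpl-2 against wild type, then hpl-2-FFAA and met-2 hpl-2 against the hpl-2 mutant. With thinned libraries met-2 hpl-2 had 5131 calls against wild type, with the width trend removed 5446, and with genes of at least 1000 bases, which are fewer, 4170.

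Replicate numbers are shared between groups, but same-numbered libraries did not deviate together: of the correlations of deviations, those over 0.1 numbered 0, 0, 0, 2 of 4 and 0 in the 5 comparisons, and in each the highest was between libraries of different numbers. With the replicate block the counts were 3453, 43, 5481, 3343 and 6479, and camera lost the maternal and germline calls in hpl-2-FFAA (adjusted p = 0.569 and 0.477 after Benjamini-Hochberg adjustment), as fbxb-82 and vet-6 lost theirs there in edgeR's test (0.139 and 0.145). Of the 55 camera calls, 0 were kept with an estimated correlation and 53 with the block, and fry gave 77 directional and 105 mixed calls; the construction of these tests differs. Without hpl-2 and met-2 in the heterochromatin and synMuv lists 48 were kept, while these lists lost their 6 calls and sex determination genes 1, in the hpl-2 mutant. The correlation of hpl-2 mutant and met-2 hpl-2 fold changes was 0.0906 among genes with a mean of at least 5 CPM, and the cause was not tested. Leaving out libraries it ran from 0.261 to 0.406, that of the hpl-2 mutant and hpl-2-FFAA from 0.5 to 0.684 and that of hpl-2-FFAA and met-2 hpl-2 from 0.276 to 0.493. The share of genes higher in hpl-2-FFAA on arms was 45.9% with arms at the outer 25%, which holds fewer genes. Of 2209 values of named genes under alternatives, 2156 kept direction and side of the threshold, 51 lost the call, 2 gained one and 0 reversed. The losses were met-2 in the hpl-2 mutant, in 7 alternatives, and genes named in hpl-2-FFAA: fbxb-82, meg-4, vet-6, sdz-28, samt-1, sdz-14, rgs-9 and fbxb-84. Depth limits the comparisons at low levels, where 3 counts are 0.202 to 0.563 CPM. Alternatives for normalized values were not run, since the values are counts.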

Other observations

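The gene groups and tests in this part were chosen after values had been seen, except the test of neighbouring genes, which was fixed before its result. Of 13 tested basement membrane genes, a list with no test of enrichment, 11 rose and 0 fell against wild type in met-2 hpl-2 (median log2 1.14), while 1 rose and 6 fell in the hpl-2 mutant. The type IV collagen genes emb-9 and let-2 rose by 3.07 and 3.35 in met-2 hpl-2, ost-1 by 3.31 and the nidogen gene nid-1 by 1.70. The laminin gene epi-1 rose by 0.57 in met-2 hpl-2 and had a log2 fold change of -0.74 in the hpl-2 mutant, where lam-1 had -0.84. Fold changes of the hpl-2 mutant and met-2 hpl-2 had r = 0.71 and -0.438 with the axis on which replicates differ, across 5740 genes, which are not independent replicates, and r = 0.107 and -0.0932 with an axis from the wild-type and met-2 hpl-2 libraries alone. With the first axis removed the median of the list went from 1.14 to 0.159 in met-2 hpl-2 and from -0.49 to 0.518 in the hpl-2 mutant. All calls here are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

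X-linked genes were more often lower in the hpl-2 mutant and more often higher in met-2 hpl-2. Of 1122 tested, 10.6% were called higher and 37% lower in the hpl-2 mutant (median log2 -0.22), 1.34% and 0.535% in hpl-2-FFAA (-0.02) and 36.3% and 19.3% in met-2 hpl-2 (0.12). In the direct comparison 33.1% were higher and 7.22% lower in hpl-2-FFAA than in the hpl-2 mutant. A mix of embryo ages is a candidate explanation for the hpl-2 mutant, though nothing measured here ties the axis along which replicates differ to age. After removal of that axis the X median lay at -0.036 relative to autosomes. In met-2 hpl-2 the X median went from 0.12 to -0.023 with that axis removed, beside -0.0154 for autosomes. That axis is carried mostly by other groups than wild type and met-2 hpl-2, whose own axis had r = 0.107 with the hpl-2 mutant's fold changes and -0.0932 with those of met-2 hpl-2.

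Of 7 genes picked for their values, acdh-1 among them, 7 were higher in met-2 hpl-2 and 5 lower in the hpl-2 mutant, with no test of enrichment. With the replicate axis removed their medians went from 2.87 to 2.27 and from -1.50 to -0.751. Against wild type acdh-2 rose by 3.75, the asparagine synthetase gene asns-2 by 2.44, tatn-1 by 2.87, sams-1 by 1.74, ins-13 by 3.54 and arrd-25 by 0.47. In the hpl-2 mutant acdh-1, acdh-2, asns-2, ins-13 and arrd-25 had log2 fold changes of -1.52, -1.75, -1.24, -1.79 and -1.50, while tatn-1 (-0.51) and sams-1 (-0.49) were not called (adjusted p = 0.237 and 0.24 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ins-13 overlaps acdh-2 on the same strand and its counts may be reads of acdh-2, at 25.6 and 25.02 CPM in met-2 hpl-2, so it may not be a separate member. The hypothesis that acdh-1 rose with the propionate shunt, the pathway it belongs to, stays open: with acdh-1 itself 3 of 4 shunt genes were called higher and 1 lower in met-2 hpl-2, and hphd-1 (0.83, SE 0.142), alh-8 (0.15, SE 0.0415) and hach-1 (-0.30, SE 0.0641), which went both ways, had a median of 0.149.

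Genes higher in the hpl-2 mutant lay next to each other more often than chance gives. Among 215 genes at least 2-fold higher with a known position there were 17 pairs of neighbouring tested genes, against a mean of 5.87 in 10000 random draws within the same chromosomes and arms or centres (permutation p = 2e-04, highest draw 17). Examples are K10G9.2 and vglu-2 on chromosome III (10285923 to 10298687 on WBcel235), where vglu-2 rose by 1.66, and gba-1 and gba-2 on chromosome II (2176741 to 2186434), which rose by 3.84 and 2.73. Of the 17 pairs, 9 lie on opposite strands, so transcription that runs on from a neighbour on the same strand may not be their only source, though duplicated copies and a count without strand stay open.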
